A study of Homo sapiens with 4 samples.

How the data were processed

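Circular RNAs (circRNAs) were profiled by nanopore sequencing in 2 human lung cell lines, IMR-90 and A549, with 2 libraries per line. Per the labels' protocols, 2 ug of total RNA entered each library, ribosomal RNA was depleted, and cDNA was made by reverse transcription that runs around the circle several times, following the CIRI-long protocol. The deposited table holds raw counts per circRNA and library, with no normalization: all values were whole numbers and the column totals differed between libraries. A circRNA is given in that table by the chromosome, start and end of its back-splice junction, in coordinates of hg19 per the submitters' processing notes. The aligner, the circRNA caller and the filters behind the table are not given in the sources used here. The smallest total of a circRNA over the 4 libraries was 2 counts. The counts come from amplified cDNA without molecular identifiers, so the intervals and floors below cover counting error only.

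The table pairs no circRNA with a gene and gives no strand. The annotation at hand was of another genome build, and coordinates were not converted, so no host gene was named and no gene list fixed beforehand was tested. Instead, circRNAs that overlapped on a chromosome were merged into loci and their counts were summed. Because strand was not given, a locus can join circRNAs of overlapping genes on both strands, and a chain of overlaps can join neighbouring genes. Genomic span was taken as the distance from start to end, introns included, and is not the length of the RNA.

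Libraries were assigned to lines and replicates by their titles. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The test used below draws its spread partly from all circRNAs or loci together. A p-value can thus be small although the item's own replicates differ. No 2 libraries were copies of one another: the chi-square statistic per degree of freedom between libraries ranged from 19.19 to 43.31. The total per library was the sum of all its circRNA counts, which ranged from 14213 to 173781.

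The lines were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, for circRNAs or loci with a total of at least 10 counts, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Shares of single circRNAs within loci were tested with diffSpliceDGE of edgeR. Normalised CPM values (counts per 1e6 counts) use the TMM factors. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Where a line had 0 counts, the fold was computed against a floor of 3 counts over both libraries of that line. It is a lower bound for counting error only, and spread between libraries can make the true fold smaller. For A549 this pooled floor rests mostly on A549 replicate 2, the deeper library. The fitted log2 fold change is not printed in these cases. For called circRNAs and loci with counts in both lines, the ratio of pooled counts over pooled totals is given with its exact 95% interval. A pooled ratio weights libraries by depth, and the fitted fold change does not. Numbers of detected circRNAs were compared after thinning every library to 14213 counts, as the mean of 100 random draws.

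The text names, per direction, up to 12 circRNAs and 12 loci past the threshold with the smallest p, the 6 loci with the smallest p for shares if any passed, and the 5 circRNAs with the highest mean CPM. Where nothing passed in a direction, the 5 smallest p in that direction were taken and are reported as not passing. For shares, where nothing passed, the 5 loci with the smallest p are named without regard to direction. These rules, the tests and most alternatives were fixed before the data were examined. The alternatives were other scalings, DESeq2 1.42.0, other count filters, the replicate number as a block, each library left out in turn, the most abundant circRNAs left out, and junctions with ends within 10 bp merged. Where a library was left out, the line with 1 library left was assumed to vary like the other.

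The tests were tried on simulated counts with 200 changed circRNAs or loci. For the tests of circRNAs and loci, the changed ones were drawn from all 6530 circRNAs or 4863 loci before the count filter. Those that then fell below it count as not recovered. With a squared coefficient of variation of 0.1, the test recovered 95.2% of the circRNAs changed 32-fold and 95.3% of such loci. Here 5749 circRNAs and 4357 loci passed the filter. With the spread of these libraries the test recovered none of the 69 circRNAs changed 32-fold and 3.03% of those changed 1024-fold. For loci these shares were 0 of 61 and 15.5%. Here 3978 circRNAs and 3349 loci passed the filter, fewer than in the data, so recovery in the data can differ. For shares within loci, none of 43 circRNAs changed 32-fold and none of 45 changed 1024-fold were recovered with the spread of these libraries, among 1526 tested, against 70.4% and 96.2% at the smaller spread, among 2458.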

Results

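Full-length circRNAs, which arise when a downstream splice donor joins an upstream acceptor, were counted in IMR-90, a line of fetal lung fibroblasts, and in A549, a line from a lung adenocarcinoma. The comparison asked which circRNAs differ between the lines. The 4 libraries held 13970 circRNAs. A549 replicate 1 held 14213 counts and A549 replicate 2 held 173781, while IMR-90 replicate 1 held 160823 and IMR-90 replicate 2 held 146199. By counting error alone, a count of 0 allowed up to 211 CPM (counts per 1e6 counts of the library) in A549 replicate 1. In the other libraries this was 17.3 to 20.5 CPM. Levels above these can lie behind a 0. Of circRNAs with 51 to 100 counts in IMR-90 replicate 1, only 33.9% were counted in IMR-90 replicate 2. Merging overlapping circRNAs gave 9189 loci, of which 6976 held 1 circRNA and 49 held 10 or more.

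A single circRNA on chromosome 20, from 52773708 to 52788209, was far more abundant in A549 than in IMR-90. It had 1882 counts in A549 replicate 1, where it was the most abundant circRNA at 13.2% of the library, and 2771 counts in A549 replicate 2, where it was at 1.59% and a circRNA on chromosome 15 led at 1.72%. IMR-90 had 1 count in replicate 1 and 0 in replicate 2. The pooled ratio was 7599, with an exact 95% interval from 1363 to 300210. The fitted log2 fold change was 13.73 (SE 0.28), though the level in A549 was 60612 ± 57526 normalised CPM (SD, n = 2). It was 12.07 without A549 replicate 1, 14.77 without A549 replicate 2 and 13.08 without IMR-90 replicate 2. Without IMR-90 replicate 1 no IMR-90 count was left. A circRNA on chromosome 1, from 27056142 to 27059283, was also higher in A549, with 305 and 286 counts against 91 and 170 in IMR-90. Its normalised level was 9236 ± 10152 CPM in A549 and 867 ± 357 in IMR-90 (SD, n = 2 each), a log2 fold change of 3.41 (SE 0.63, adjusted p = 0.00021 in edgeR's quasi-likelihood test). The pooled ratio, in which the deep A549 library weighs most, was lower, at 3.70 (exact 95% interval 3.19 to 4.29). These 2 circRNAs were the only ones of 6530 tested to pass the threshold in edgeR, and 95 had an unadjusted p under 0.05. With DESeq2 0 circRNAs passed, with log2 fold changes of 14.23 and 3.56 and adjusted p of 0.17 and 0.59 for the circRNAs on chromosomes 20 and 1, and 227 had an unadjusted p under 0.05. The call on chromosome 1 rested on the shallow A549 library: without A549 replicate 1 its log2 fold change was 1.09 and its adjusted p 0.67 in edgeR, and it also ended without IMR-90 replicate 1 (0.44) or IMR-90 replicate 2 (0.48), where the log2 fold change was 3.27 and 4.11. Over all alternatives its adjusted p ranged from 1.8e-36 to 0.67, and that of the chromosome 20 circRNA from 0 to 0.56. Leaving out A549 replicate 1 gave 9 called circRNAs, 3 higher and 6 lower in A549, leaving out A549 replicate 2 gave 19, all higher, and leaving out either IMR-90 library gave 1.

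No circRNA passed as lower in A549. The smallest p in that direction belonged to a circRNA of 362 bp on chromosome 5, from 33881224 to 33881585, with 287 and 257 counts in IMR-90 and 0 in both A549 libraries (adjusted p = 0.24 in edgeR). A circRNA on chromosome 9, from 137582758 to 137593179, had 514 and 159 counts in IMR-90 against 1 and 0 in A549 (adjusted p = 0.58). Without A549 replicate 1 both passed in edgeR, with adjusted p of 0.015 on chromosome 5 and 0.00023 on chromosome 9, against up to 0.66 over all alternatives for both. A further 3 circRNAs had 0 counts in A549 and an adjusted p of 0.61. They lay on chromosome 12 from 6657591 to 6657991, with 321 and 94 counts in IMR-90, on chromosome 1 from 59787208 to 59844509, with 99 and 321, and on chromosome 1 from 246350045 to 246350244, with 371 and 0.

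Summed over loci, 16 of 4863 tested loci differed between the lines in edgeR, 11 higher in A549 and 5 lower, and 168 had an unadjusted p under 0.05. The locus of the abundant circRNA on chromosome 20 led, with 1885 and 2949 counts in A549 against 1 and 0 in IMR-90. It held 6 circRNAs, and that one made up 96.3% of its counts. The chromosome 1 locus from 27056142 to 27059283 had 307 and 421 counts against 93 and 170, a log2 fold change of 3.58 (SE 0.63, adjusted p = 2.8e-05 in edgeR) and a pooled ratio of 4.52 (exact 95% interval 3.92 to 5.23). Its log2 fold change was 1.71 without A549 replicate 1 (adjusted p = 0.69 in edgeR) and 3.33 without IMR-90 replicate 1 (0.13), and DESeq2 gave an adjusted p of 0.86, in a range from 7.7e-12 to 0.86 over all alternatives. Of the 11 loci higher in A549, 8 had no count in either IMR-90 library. Their adjusted p in edgeR ranged from 0.00018 to 0.03, and how far the calls rested on single libraries is given below. Among these, the locus on chromosome 11 from 22225350 to 22261230 had 31 and 229 counts and was at least 142-fold higher. The locus on chromosome 9 from 43815785 to 43885072 had 55 and 151 counts over 7 circRNAs and was at least 112-fold higher. The locus on chromosome 17 from 96902 to 183725 had 57 and 108 counts and was at least 89.8-fold higher. On chromosome 5, from 1266579 to 1282739, 57 and 77 counts gave an increase of at least 72.9-fold. These were 0.401% of A549 replicate 1 and 0.0443% of A549 replicate 2, so the size of the bound depends on the library. The leading circRNA of the locus, from 1278756 to 1282739, had 102 of the 134 counts. A second locus on chromosome 20, from 5939174 to 5966777, had 52 and 75 counts, and none of its 5 circRNAs was counted in both A549 libraries. The remaining 3 lay on chromosome 1 from 236998847 to 237026854 (40 and 69 counts), on chromosome 10 from 6255717 to 6257163 (53 and 32) and on chromosome 2 from 241511840 to 241515027 (45 and 0). None of the 3 circRNAs of the chromosome 1 locus was counted in both A549 libraries. The chromosome 2 locus was counted in 1 library only, yet it passed (adjusted p = 0.03 in edgeR). With the replicate number as a block, the loci on chromosomes 1, 10 and 2 missed the threshold in edgeR (adjusted p of 0.12, 0.065 and 0.73). The others of the 8 passed. On chromosome 11, from 68115315 to 68157520, the counts were 41 and 271 against 0 and 2, a ratio of 255 with an exact 95% interval from 69.9 to 2113.

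**Figure D1:**
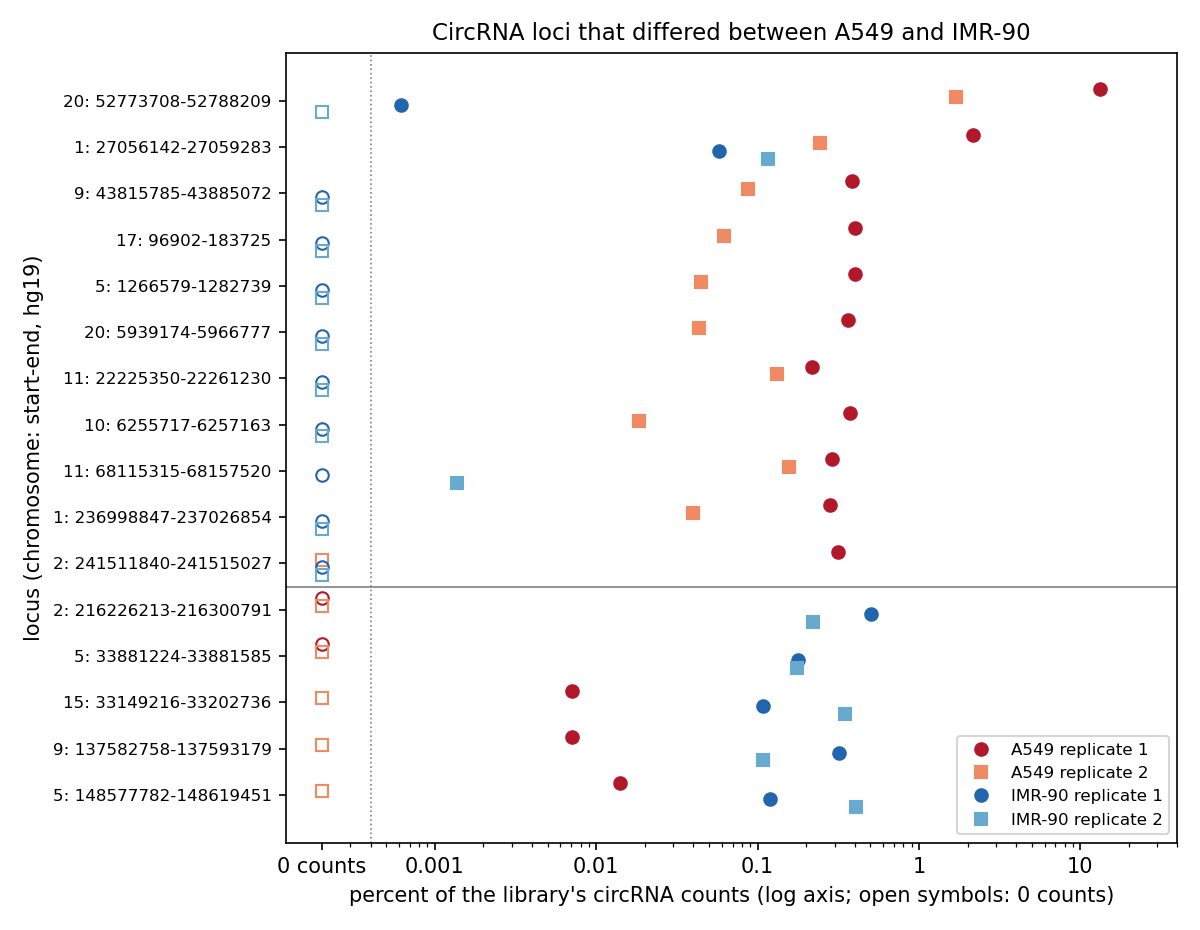
Percent of each library's circRNA counts (log axis) at the 16 loci past the threshold, given by chromosome, start and end in hg19, with 1 symbol per library and open symbols at the left edge for 0 counts. The 11 loci above the line were higher in A549 and the 5 below it lower, and the chromosome 20 locus reached 13.3% of A549 replicate 1 and 1.70% of A549 replicate 2.

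The locus lower in A549 with the smallest p was also the one with the most circRNAs. On chromosome 2, from 216226213 to 216300791, 71 circRNAs gave 816 and 322 counts in IMR-90 and 0 in both A549 libraries. By the pooled floor the locus was at least 232-fold lower in A549 (adjusted p = 1.8e-07 in edgeR). That bound rests mostly on A549 replicate 2. A 0 in A549 replicate 1 alone allowed up to 211 CPM by counting error, against 3751 ± 2264 normalised CPM in IMR-90 (SD, n = 2). No single circRNA carried the locus: the highest count of any was 110, or 9.67% of the locus total. A start or an end was shared with another circRNA by 33.8% of the 71. Of the 71 circRNAs, 39 were counted in IMR-90 replicate 1 alone, 24 in replicate 2 alone and 8 in both, and their spans reached 27577 bp. The chromosome 5 circRNA from 33881224 to 33881585 formed a locus of its own. By the pooled floor it was at least 111-fold lower in A549 (adjusted p = 0.0083 in edgeR). This bound, too, rests mostly on A549 replicate 2, as its level in IMR-90 was 1799 ± 117 normalised CPM (SD, n = 2). The locus on chromosome 15 from 33149216 to 33202736 had 684 counts in IMR-90 against 1 in A549, a pooled ratio of 419 with an exact 95% interval from 74.9 to 16567. The chromosome 9 locus from 137582758 to 137593179 had 514 and 159 counts against 1 and 0, a ratio of 412 (73.7 to 16301). On chromosome 5, from 148577782 to 148619451, 192 and 594 counts stood against 2 and 0, a ratio of 241 (66.4 to 1991), and a circRNA of 22575 bp made up 74.9% of them. These pooled ratios rest mostly on the deep A549 library: the fitted log2 fold changes in edgeR were -7.19, -7.15 and -6.00 for the loci on chromosomes 15, 9 and 5, and without A549 replicate 2 they were -5.01, -4.96 and -4.22, with adjusted p of 0.58, 0.65 and 0.65. Among other settings, the calls also ended without IMR-90 replicate 2 on chromosome 15 (0.50), without IMR-90 replicate 1 on chromosome 9 (0.48), without either on chromosome 5 (0.054 and 0.50), and with DESeq2 on all 3 (0.29, 0.29 and 0.65). Over all alternatives their adjusted p ranged from 0.0044 to 0.58, from 0.0059 to 0.65 and from 0.00056 to 0.65.

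**Figure D2:**
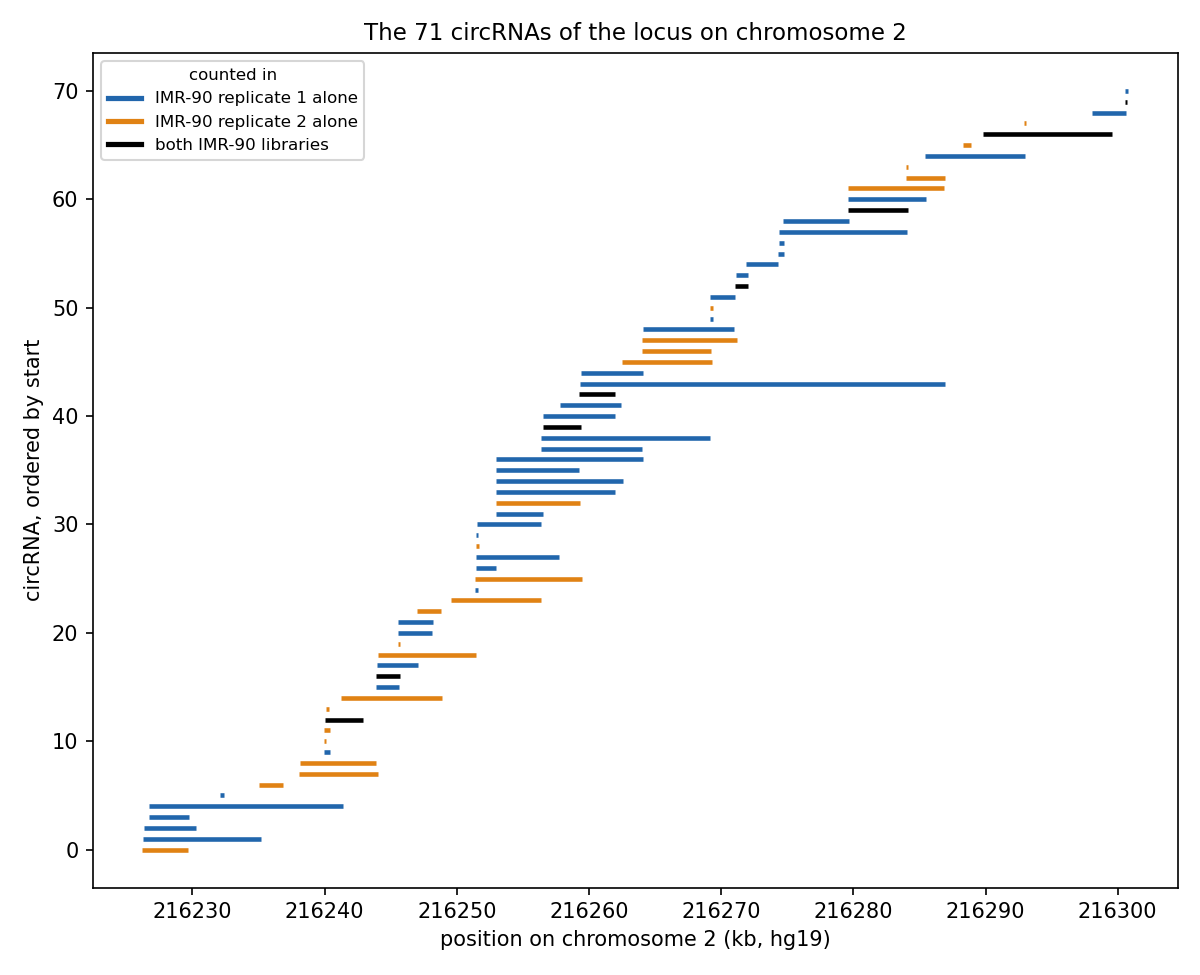
Map of the chromosome 2 locus from 216226213 to 216300791 (x axis, position in kb in hg19), with 1 bar from start to end for each of its 71 circRNAs in order of their starts (y axis), coloured by the IMR-90 libraries that counted it. The bars cover the whole locus because loci were built from overlapping circRNAs, and 8 of the 71 circRNAs were counted in both libraries.

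The number of called loci depended on single libraries. Without A549 replicate 1, 6 loci passed, 2 higher and 4 lower, and 5 of the 16 were kept, the chromosome 20 locus from 52773708 to 52788209 being the only one of the 11 higher loci among them. Without A549 replicate 2, 23 loci passed and 12 of the 16 were kept, without IMR-90 replicate 1, 7 passed and 6 were kept, and without IMR-90 replicate 2, 11 passed and 9 were kept. The chromosome 2 locus with 71 circRNAs missed the threshold only without IMR-90 replicate 1 (adjusted p = 0.054 in edgeR, and as low as 3.0e-12 in other alternatives). The chromosome 20 locus from 52773708 to 52788209 passed whichever library was left out, but with a robust spread estimate, a setting chosen after seeing the data, its adjusted p was 0.57 in edgeR, within a range from 0 to 0.62 over all alternatives, the upper end being that without the 10 most abundant circRNAs, which removes the circRNA that made up most of the locus. The chromosome 5 locus from 33881224 to 33881585 passed in none of the fits that left out a library.

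The lines were also compared for which circRNA of a locus they made most of. Over 2848 circRNAs in 1013 loci, 0 passed the threshold in edgeR's diffSpliceDGE, and 33 had an unadjusted p under 0.05. In the simulation with the spread of these libraries, this test recovered none of 45 circRNAs changed 1024-fold. The absence of calls therefore does not show that the lines shared the same proportions. On chromosome 15, in the locus from 43102812 to 43132631, IMR-90 replicate 2 had 157 counts of the circRNA from 43102812 to 43109295 and none of the circRNA from 43109230 to 43132631, while A549 replicate 2 had 105 counts of the latter and none of the former. Neither was counted in A549 replicate 1 or IMR-90 replicate 1, so that contrast rests on 1 library per line. In the locus on chromosome 17 from 78301616 to 78310178, both A549 libraries counted the circRNA from 78305806 to 78310178 (12 and 85 counts) and neither IMR-90 library did. IMR-90 replicate 2 had 72 counts of the circRNA from 78301616 to 78306431. IMR-90 replicate 1 had no count in the locus, so the contrast rests on IMR-90 replicate 2 alone. The other loci among the 5 with the smallest p lay on chromosome 18 from 12999420 to 13019205, on chromosome 13 from 114806476 to 114839312 and on chromosome 12 from 21790005 to 21807536. The adjusted p per locus was 0.98 for all 5.

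Of the circRNAs with the highest mean level, 3 did not differ past the threshold. The circRNA on chromosome 3 from 169863211 to 169867032 was at 11681 ± 8224 normalised CPM in A549 and 11354 ± 1619 in IMR-90 (SD, n = 2 each, adjusted p = 0.95 in edgeR), and the sign of its difference turned with the scaling. On chromosome 15, the circRNA from 80412670 to 80415142 was at 16514 ± 7066 and 8854 ± 511 and did not pass in edgeR (log2 fold change 0.90, SE 0.31, adjusted p = 0.61), but it passed without A549 replicate 1 (adjusted p = 1.6e-10, against up to 0.84 over all alternatives). On chromosome 6, the circRNA from 4891947 to 4892613 was at 9617 ± 205 and 4956 ± 2326, with a log2 fold change of 0.96 (SE 0.45, adjusted p = 0.61 in edgeR), and it passed without A549 replicate 2 (adjusted p = 0.043, against up to 0.82). The 2 others among the 5 highest were the called circRNAs on chromosomes 20 and 1.

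Most circRNAs were counted in a single library. Of the 13970, 10301 (73.7%) were found in 1 library and 642 (4.60%) in all 4, and these 642 held 33.2% to 38.5% of each library's counts. The circRNAs found in both libraries of one line and in neither of the other numbered 492 for A549 and 487 for IMR-90, 979 together. Pairing the libraries across the lines instead gave 587 and 565. Over the 642 shared circRNAs, Pearson's correlation of log2(CPM + 1), across circRNAs, which are not independent replicates, was 0.49 between the A549 libraries and 0.53 between the IMR-90 libraries, and 0.36 to 0.39 across the lines. Over all circRNAs, absent ones included, it was 0.16 between the A549 libraries and 0.037 between the IMR-90 libraries. Across the lines it was 0.11 and 0.15 for the shallow A549 replicate 1 and -0.15 and -0.13 for A549 replicate 2. The IMR-90 pair thus lay above the pairs with the deep A549 library and below those with the shallow one. A circRNA with 51 to 100 counts in IMR-90 replicate 1 was found in IMR-90 replicate 2 in 33.9% of cases, and one with over 200 counts in 90.6%.

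**Figure D3:**
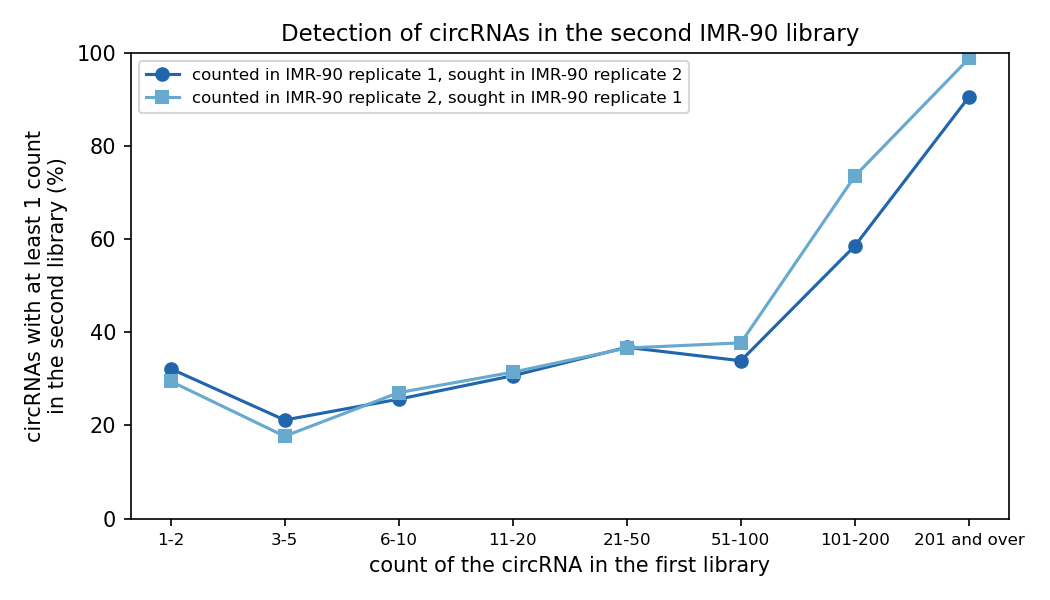
Percent of circRNAs with at least 1 count in the second IMR-90 library (y axis) by their count in the first (x axis), with 1 line for each order of the libraries. Both lines stay under 40% up to 100 counts and reach 90.6% and 98.8% above 200.

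Thinned to 14213 counts, 2718 and 3524 circRNAs were detected in the A549 libraries and 2904 and 2994 in the IMR-90 libraries. The difference of the means, 172, was smaller than the range between the A549 libraries, and without A549 replicate 2 its sign turned (-231). It also turned with a minimum of 5 counts (-178). With 2 libraries per line no exact test could reach the threshold.

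By genomic span, circRNAs of 1 to 10 kb held 39.3% and 45.7% of counts in A549 and 44.8% and 45.1% in IMR-90. Those of 10 to 100 kb held 46.4% of counts in A549 replicate 1, against 24.6% in A549 replicate 2 and 24.2% and 27.2% in IMR-90. The difference between the lines in that class, 9.81 percentage points, was smaller than the spread between the A549 libraries (SD 15.4). It turned sign without A549 replicate 1 (-1.08) and was 20.7 without A549 replicate 2. CircRNAs under 200 bp held 0.612% of A549 replicate 1 and 2.47% to 4.82% of the other libraries.

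**Figure D4:**
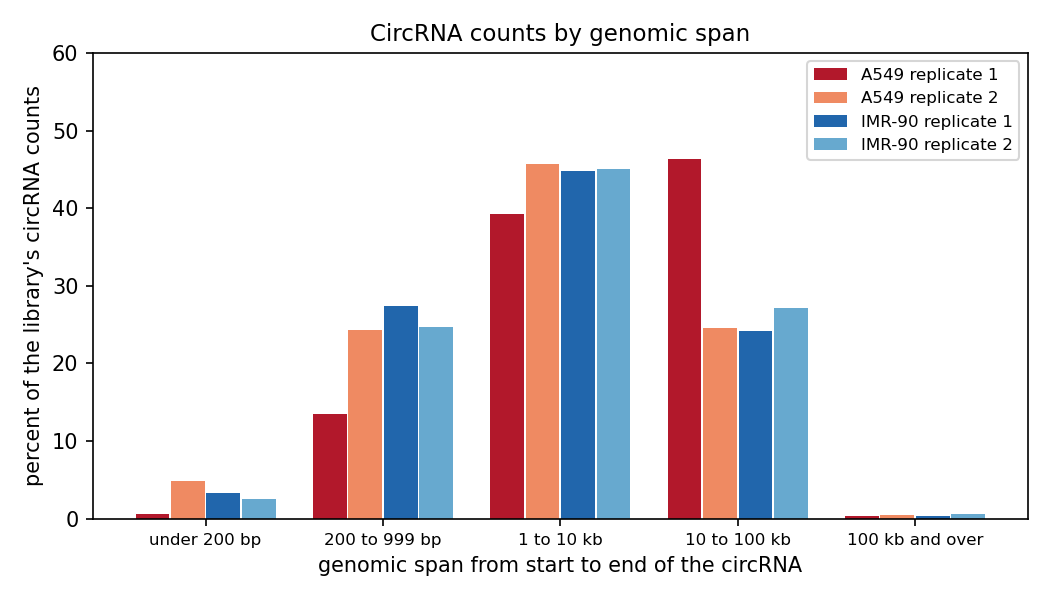
Percent of each library's circRNA counts (y axis) by genomic span from start to end (x axis), with 1 bar per library. A549 replicate 1 stands at 46.4% in the class from 10 to 100 kb, where the other 3 libraries lie between 24.2% and 27.2%.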

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

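Against 2 circRNAs past the threshold, RLE factors gave 4, library totals alone 6, a minimum of 20 counts 5, no filter 1, DESeq2 0, the filterByExpr filter 0, and leaving out the 10 most abundant circRNAs 0, since that removes both called circRNAs. A robust spread estimate, added after seeing the data, gave 0. Leaving out each library gave 1 to 19, and the 19 (without A549 replicate 2) were all higher in A549. Upper-quartile factors could not be fitted for circRNAs, as the upper quartile of A549 replicate 1 was 0. Against 16 loci (11 higher, 5 lower), a minimum of 20 counts gave 25, leaving out the most abundant circRNA of each locus 4, and leaving out each library 6 to 23. Upper-quartile factors gave 24 loci (23 higher, 1 lower) and moved the median log2 fold change of all loci from -0.87 to -0.34. DESeq2 gave 12 loci (11 higher, 1 lower), and library totals alone 24 (18 higher, 6 lower). Other than where named, the cause was not tested.

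With the replicate number as a block, 1 circRNA and 9 loci (8 higher, 1 lower) passed. The deviations of same-numbered libraries from their line means correlated at 0.0058 over circRNAs and 0.018 over loci. These values do not decide whether the numbers pair the libraries, as even libraries of one line agreed weakly. Pearson's correlation over all circRNAs was 0.16 between the A549 libraries and 0.037 between the IMR-90 libraries.

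For shares within loci, 0 circRNAs passed in each alternative run. As the main test recovered none of the simulated 1024-fold changes with the spread of these libraries, this does not show a stable result. Of the named circRNAs and loci, the chromosome 3 circRNA from 169863211 to 169867032, which was not called, turned its direction: its log2 fold change was 0.042, and -0.043 with RLE factors, -0.029 with library totals alone, -0.044 with DESeq2, -0.083 with no filter, -0.15 with the replicate block, and between -0.63 and 0.47 with each library left out; the cause was not tested. Leaving out each library gave differences in detection of -231 to 575 and in the class from 10 to 100 kb of -1.08 to 20.7 percentage points, so their direction rests on single A549 libraries. The gene lists and their alternatives were not run. Depth limits A549 replicate 1, where an absent locus can stand at up to 211 CPM by counting error alone.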

Other observations

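The tests of sampling, of copied molecules, of proportional variation, of ends displaced by up to 100 bp and of one dominant circRNA were chosen only after the results they bear on were seen. Compact loci with many circRNAs were chosen after their values were seen, and their class boundaries were set then. Loci with 10 or more circRNAs fell into 16 of under 10 kb, with 270 circRNAs, and 33 longer ones, with 489. The most crowded compact loci lay on chromosome 17 from 79477055 to 79479807 (37 circRNAs, with 37 and 304 counts in A549 and 1035 and 144 in IMR-90), on chromosome 7 from 5566798 to 5570214 (29 circRNAs) and on chromosome 6 from 74227238 to 74229779 (26 circRNAs). A compact locus on chromosome 17, from 48262796 to 48264236, had 106 and 154 counts in IMR-90 and none in A549. The circRNAs of compact loci had a median span of 580.5 bp and 26.7% of them shared a start or an end with another circRNA, against 8915 bp and 66.7% in the longer loci. Ends joined away from splice sites were set to need under 20% and to be excluded over 50%, so 26.7% leaves that explanation undecided. Among the longer loci, those on chromosome 21 from 47410180 to 47423974 and on chromosome 7 from 128477494 to 128491525 also had no A549 count, against 82 and 104 and against 148 and 34 in IMR-90. These 3 loci without an A549 count did not pass in edgeR. In the longer loci on chromosomes 21 and 7, 33.3% and 18.2% of circRNAs shared a start or an end. In the called chromosome 2 locus of 71 circRNAs 33.8% did. These shares lie below the 66.7% of all longer loci, and ends joined away from splice sites were not tested there.

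Most circRNAs of one IMR-90 library were absent from the other, even at counts where chance sampling would find them. Of those with a depth-scaled mean of 20 to 50 counts, 72.2% were absent from one of the 2 libraries, which argues against sampling of independent reads. Between A549 replicate 2 and the IMR-90 libraries it was 77.8% and 73.2%, about as many. Between the A549 libraries it was 13.0% of 54. That pair was scaled to the shallow library, where the same counts stand for higher levels, so its share is not comparable. At 200 to 500 counts, a closer level, 0 of 65 circRNAs were absent from one of the 2 IMR-90 libraries. Imprecise junction ends are argued against as the main cause, since of the 10301 circRNAs of a single library 0% had a circRNA of another library within 10 bp at both ends and 2.90% within 100 bp. Variation in proportion to the level would keep the squared coefficient of variation constant, but its value at 200 counts and over was 0.139 times that at 50 to 100 counts (bootstrap 95% interval 0.080 to 0.227). A candidate explanation that stays open is that counts are copies of few captured molecules, which would keep the excess variance over the mean constant: the ratio was 0.730, but its interval (0.464 to 1.11) reached below the limit of 0.5 set for it, and other differences between the replicates were not tested.

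A549 replicate 1 held 46.4% of its counts in circRNAs of 10 to 100 kb. Lower depth is argued against, as 100 draws of A549 replicate 2 thinned to the same total reached at most 25.3%. The abundant chromosome 20 circRNA is argued against as the whole cause, as 38.2% remained without it, against 23.4% to 27.2% in the other libraries. The pattern is in 1 library, and no biological explanation was tested.

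The chromosome 20 circRNA took 8.30 times as large a share of A549 replicate 1 as of A549 replicate 2. Sampling of independent reads is argued against by the lower exact 95% bound of this ratio, 7.83. Of the 143 circRNAs counted in both A549 libraries with a depth-scaled mean of 10 or more, 22 (15.4%) had a ratio as large, itself included. At a mean of 100 or more it was 2 of 5, itself included, too few to decide, and ordinary spread between these libraries stays open.

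The real grouping called 2 circRNAs and 16 loci, and the highest of the other splits called 1 circRNA and 1 locus. In both cases 1 of the 3 splits, the real one, gave as many, and 3 splits are too few for a share under 0.05.

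A hypothesis that whole chromosomes differ, as gains or losses in a cancer line could cause, found 0 of 23 chromosomes past the threshold in camera on the loci, with lowest adjusted p of 0.83 with a preset correlation and 0.996 with an estimated correlation. The mean log2 fold changes did not all lie near 0, as excluding the hypothesis would need: the loci of chromosome 1 were at -1.38. The SE of that mean, 0.24, reflects the spread over 474 loci, which are not independent replicates. These means move with the libraries, as the median of all loci went from -0.87 to -1.05 without A549 replicate 1, -5.42 without A549 replicate 2, and 1.15 and 1.04 without IMR-90 replicate 1 or 2, so the hypothesis stays open. Mitochondrial circRNAs, 53 in number, held 0.042% and 0.091% of counts in A549 and 0.152% and 0.070% in IMR-90, and 37 of the 53 were found in 1 library.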
